A study of Arabidopsis thaliana with 8 samples.

How the data were processed

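The series holds 8 RNA-seq libraries of Arabidopsis thaliana, made from whole seedlings 5 days old. Per the labels, seeds were kept at 4 °C for 4 days and then grown at 22 °C in cycles of 16 h light and 8 h dark. Total RNA was purified with an RNeasy Plant Mini kit and libraries came from an Illumina TruSeq RNA kit. The labels give 3 libraries of the wild type Col-0, 2 of a line that overexpresses MIR394A (MIR394A_OE) and 3 of bin2-1, a dominant mutant of the brassinosteroid signalling kinase BIN2. Nothing in the labels says that replicates came from separate sowings, so the p-values measure the spread between these samples, which may be technical.

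The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of a library), per the file headers and the labels, with 2 decimals. Bowtie2 and HISAT are named in the submitters' processing notes, without a role. Their versions, the program that computed FPKM, the genome build and the use of strand are not given in the sources used here. The table lists 22951 genes by NCBI gene number, each above 0 in at least 1 library. Of these, 22798 matched the TAIR10.1 gene table, which was used for names and neighbours, and 153 did not. MIR394A and MIR394B were not analysed here, since neither gene was among those listed.

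Sequencing depth was estimated from the smallest steps between low FPKM values, since 1 read on a gene of known length is worth a fixed amount. Over 1646 genes with lengths of 500 to 1800 nt, the estimate was 9.69 to 11.2 M reads per library. Of the values worth up to 5 reads, 86.2% to 90.8% came out whole within 0.1 read, against 20.0% by chance. At this depth 3 reads on 1 kb of transcript correspond to 0.268 to 0.310 FPKM, so levels near these values rest on very few reads. This floor covers counting error only.

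FPKM values are not counts, so they were tested on the log2 scale with limma 3.58.1 in R 4.3.3. A pseudocount of 1 FPKM was added, which understates fold changes of genes with low values, and genes with a mean of at least 1 FPKM over the 8 libraries were kept, which left 18798. All 8 libraries entered 1 fit with a mean per group (lmFit, eBayes with trend and robust), so that the 2 MIR394A_OE libraries shared the spread of the other groups. The p-values are two-sided and were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The error of a log2 fold change is its standard error (SE), and group levels are means of FPKM with their SD.

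Gene lists were fixed before the data were examined. There were 25 lists of known loci with 339 members, of which 333 were in the table, and 8 families taken by gene symbol or synonym. Matching by symbol also took in genes of other families, and the lists were tested as fixed and again without these. The 32 lists with at least 3 tested members were compared with all other genes by limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test was repeated with a correlation estimated for each list. Median, mean and test differed in sign for 6, 5 and 7 lists of the 3 comparisons (MIR394A_OE with Col-0, bin2-1 with Col-0, MIR394A_OE with bin2-1), none of which passed. Members were also counted after adjustment over the list alone. The genes named in the text follow a rule fixed in advance. It takes LCR and BIN2, then up to 8 called genes each way in a comparison with Col-0 (5 between the mutant lines) by size of change, with at least 5 FPKM in the higher group and no overlap between groups. From each list it takes up to 4 called members, or 2 with the smallest p where none was called. Members counted after adjustment over the list alone were named after their values were seen, as were HEI10, the clock and iron genes and the genes of the closing observations.

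Alternatives covered the pseudocount, the filter, the scaling (median of ratios, quantiles), the replicate number as a block, the groups in the fit, the form of eBayes, a minimum fold change and leaving out each library in turn. A threshold of 0.10, library weights estimated by limma, the families without members of other families (also with each library left out and with both rescalings), a fit without the 2 libraries lowest on the first principal component and a covariance of the 2 responses against separate Col-0 libraries were chosen after seeing the data.

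The test was tried on simulated log2 values for the 18798 genes, drawn from the real means and spreads with independent noise, with 200 genes above 5 FPKM changed in each of 20 runs. For MIR394A_OE against Col-0, 49.7% of genes changed by 1 on the log2 scale were recovered, 90.0% at 1.5 and 96.5% at 2. For bin2-1 against Col-0 the shares were 65.5%, 95.3% and 97.5%, and for MIR394A_OE against bin2-1 they were 50.8%, 88.9% and 95.3%. False calls made up 5.5%, 5.9% and 6.6% of calls in these 3 comparisons. These shares hold for 200 changed genes and independent noise. With fewer changed genes the adjusted threshold is stricter, so the shares do not carry over to a comparison with 2 calls. In the data HEI10, at a log2 fold change of -1.88, was not called in MIR394A_OE against Col-0 (limma, adjusted p = 0.0823). The mature miR394 sequence was read from the TAIR10.1 annotation and searched without gaps in the annotated transcripts of 22792 genes, scoring 1 per mismatch and 0.5 per G:U pair. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.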

Results

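Gene expression was measured in whole light-grown seedlings of Col-0, MIR394A_OE and bin2-1. The series asks how miR394, a small RNA, and its target gene act on brassinosteroid signalling, the steroid hormone pathway that drives elongation of the hypocotyl. The estimated depth lay between 9.69 and 11.2 M reads in the 8 libraries, so depth differed little between groups.

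The first principal component held 43.1% of the variance and placed the 3 bin2-1 libraries at 30.9 to 38.6. Col-0 replicate 1 lay at -35.4 and MIR394A_OE replicate 1 at -54.2, while MIR394A_OE replicate 2 lay at -2.9. The MIR394A_OE replicates correlated at r = 0.952 across genes, with 1382 genes more than 2-fold apart. MIR394A_OE replicate 2 and Col-0 replicate 2 correlated at 0.982, with 301 such genes. These correlations are across genes, which are not independent replicates.

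**Figure D1:**
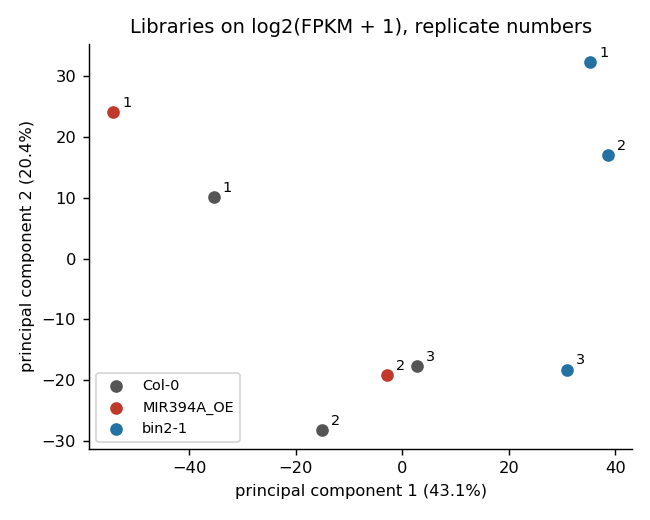
Principal components of log2(FPKM + 1) over the tested genes, 1 point per library with its replicate number. The 3 bin2-1 libraries lie between 30.9 and 38.6 on component 1, and MIR394A_OE replicate 1 lies at -54.2, apart from replicate 2 at -2.9.

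LCR (AT1G27340), the F-box gene targeted by miR394, was read first because it bears on the label of the overexpressor. Its level was 17.3 ± 0.226 FPKM (SD, n = 2) in MIR394A_OE and 21.03 ± 2.45 FPKM (SD, n = 3) in Col-0. The library values were 17.15 and 17.47 FPKM in MIR394A_OE against 19.62, 19.62 and 23.86 in Col-0, lower in 2 of 2 libraries. In bin2-1 they were 27.01, 23.85 and 15.97 FPKM, the last below both MIR394A_OE libraries. The log2 fold change of LCR was -0.26 (SE 0.22, 95% interval -0.77 to 0.24) and did not pass the test (limma, adjusted p = 0.874). The LCR transcript carries a site for miR394 (TTGGCATTCTGTCCACCTCC in DNA letters) with the sequence GGAGGTTGACAGAATGCCAA, at chromosome 1, 9497605 to 9497624 on the plus strand in TAIR10.1. The site lies in the coding part of exon 2 of 2 and has a mismatch score of 1.0, the lowest among the genes searched. BIN2, whose bin2-1 allele is a point mutation, was at 102 ± 8.58 FPKM in Col-0, 84.5 ± 28.9 in MIR394A_OE and 100 ± 9.65 in bin2-1, with no call (adjusted p = 0.873 and 0.952), and it checks no label.

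The comparison of MIR394A_OE with Col-0 asks what differs in the line labelled as overexpressing MIR394A. The overexpression itself could not be checked from these values, since MIR394A was not analysed here and LCR was not called. MRD1 (AT1G53480) fell from 35.6 ± 4.99 FPKM (SD, n = 3) to 3.58 ± 1.91 (SD, n = 2), a log2 fold change of -3.06 (SE 0.25, limma, adjusted p = 0.00686). ABCB19 (AT3G28860), a transporter of auxin out of cells, fell from 37.5 ± 6.10 to 7.21 ± 2.55 FPKM, a log2 fold change of -2.25 (SE 0.22, adjusted p = 0.0195). HEI10, a meiotic crossover gene that neighbours MRD1, had a log2 fold change of -1.88 (SE 0.23) and missed the threshold (adjusted p = 0.0823). In TAIR10.1 MRD1 and HEI10 overlap on opposite strands, so without strand information their reads may be shared and their separate levels are uncertain. All 3 genes were lower in 2 of 2 MIR394A_OE libraries than in every Col-0 library.

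In all, 2 of 18798 genes passed, 0 higher and 2 lower, while 898 had an unadjusted p under 0.05, against 940 by chance. MRD1 kept its call in 7 of the 8 fits that left out a library (without Col-0 replicate 3, adjusted p = 0.0541) and ABCB19 in 1 of them, that without MIR394A_OE replicate 1. For ABCB19 the adjusted p was 0.102, 0.156 and 0.0541 without Col-0 replicate 1, 2 and 3, 0.0901 without MIR394A_OE replicate 2, and 0.0623, 0.0801 and 0.0592 without bin2-1 replicate 1, 2 and 3. A limma fit of these 2 groups alone called 0 genes (adjusted p = 0.128 for MRD1 and 0.228 for ABCB19; 572 genes at an unadjusted p under 0.05), and the same 2 genes were called without both libraries lowest on component 1.

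**Figure D2:**
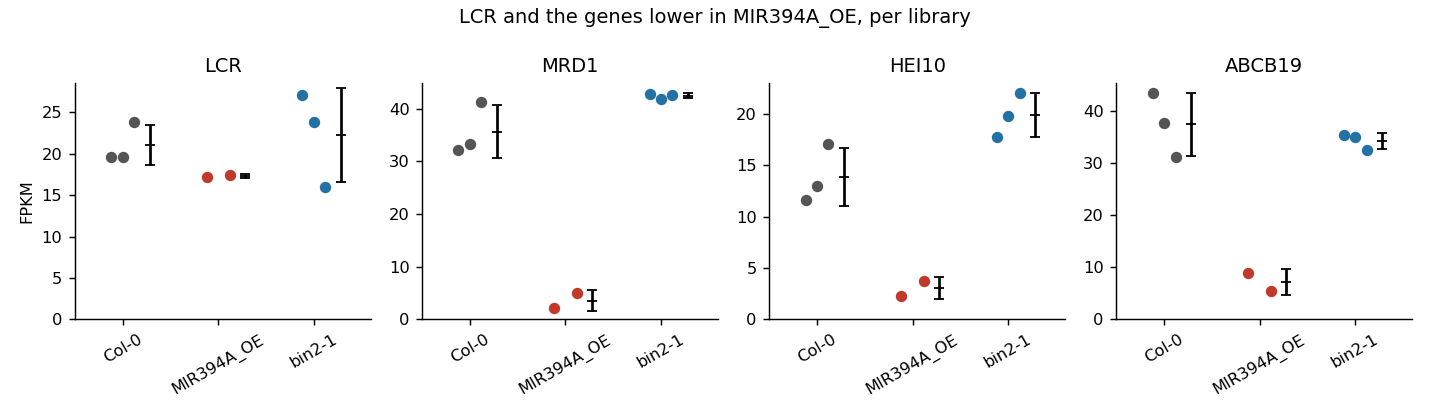
FPKM of LCR, MRD1, HEI10 and ABCB19 in each library by genotype, with the group mean and SD as a bar at the right of the points. MRD1 lies at 2.23 and 4.93 FPKM in MIR394A_OE and at 32.18 to 41.34 in Col-0, while LCR lies at 17.15 and 17.47 in MIR394A_OE.

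Growth-associated SAUR genes, small auxin-induced genes linked to cell elongation, were the list with the largest shift in MIR394A_OE. Their median log2 fold change was 0.83 over 15 tested members, 14 of them positive, and the list passed camera (adjusted p = 3.61e-08; adjusted p = 0.570 with an estimated correlation). None of the 15 passed over all genes, and 5 rose when adjusted over the list alone. They were SAUR67 (log2 fold change 1.27, SE 0.26), SAUR62 (1.18, SE 0.35), SAUR64 (1.15, SE 0.35), SAUR66 (1.06, SE 0.33) and SAUR15 (1.14, SE 0.39). Levels were low: SAUR67 lay at 1.42 to 1.54 FPKM in Col-0 and at 4.82 and 5.24 in MIR394A_OE. SAUR62 lay at 2.41 to 5.56 FPKM in Col-0 and at 7.14 and 12.12 in MIR394A_OE. Members of the SAUR clusters are near copies of each other, so reads may be shared among them. The family of all SAUR genes, with AT5G01830, an ARM repeat protein taken in by its synonym, also passed (53 members, median 0.26, adjusted p = 0.000775; adjusted p = 0.570 with an estimated correlation), with 0 called over all genes and 1, SAUR67, adjusted over the list alone. The family lost its call without Col-0 replicate 1 (adjusted p = 0.177), also with AT5G01830 removed (0.131).

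The Aux/IAA list, most of whose members are early auxin-induced repressors, passed upward (25 members, median 0.25, adjusted p = 0.0438; adjusted p = 0.691 with an estimated correlation). It also holds MP, NPH4 and ARF19, auxin response factors that carry IAA synonyms, and passed without them (22 members, median 0.28, adjusted p = 0.0142; adjusted p = 0.691 with an estimated correlation). IAA4 had a log2 fold change of 0.61 (SE 0.23) and IAA7 of 0.40 (SE 0.17). Cell division markers passed upward (13 members, median 0.29, adjusted p = 0.0438; adjusted p = 0.765 with an estimated correlation), with KN at 0.50 (SE 0.22) and CYCB1;2 at 0.37 (SE 0.18). Primary wall cellulose synthesis genes passed downward (8 members, median -0.35, adjusted p = 0.0172; adjusted p = 0.765 with an estimated correlation), with CESA1 at -0.46 (SE 0.27) and CSI1 at -0.59 (SE 0.44). In these 3 lists limma called 0 members over all genes and 0 adjusted over the list alone. CESA1 was at 70.62 FPKM in MIR394A_OE replicate 1 and 134.23 in replicate 2, and without replicate 1 the cellulose list turned upward (adjusted p = 0.405) and cell division markers lost their call (adjusted p = 0.422). The Aux/IAA call was lost without Col-0 replicate 1, 2 or 3 (adjusted p = 0.0867, 0.0684 and 0.0506) and without either MIR394A_OE replicate (0.0987 and 0.145), and that of the 22 without the factors without MIR394A_OE replicate 1 (0.397). Cellulose and cell division lists also lost theirs without Col-0 replicate 2 (0.0543 and 0.150) or 3 (both 0.0804).

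Brassinosteroid biosynthesis genes did not pass in MIR394A_OE (9 members, median -0.09, adjusted p = 0.653), with DET2 at -0.28 (SE 0.19) and DWF4 at 0.26 (SE 0.20). PRE and BEE growth factors were positive in 9 of 9 members, at a median of 0.33, without passing (adjusted p = 0.0598), and HBI1 among them had a log2 fold change of 0.71 (SE 0.31). Of the 32 lists, 5 passed, 4 upward and 1 downward, and quantile scaling gave 4 and 2. The other 27 had adjusted p between 0.0590, for root and root hair markers, and 0.941, for expansins. Markers of the time of harvest did not pass as a list (adjusted p = 0.830), while TOC1 was at 30.5 FPKM and GI at 9.34 in MIR394A_OE replicate 1, against 66.54 and 23.51 in replicate 2. Camera tests a shift of a whole list to 1 side. With 6 members positive and 6 negative, opposite moves of clock genes would not show in it. Without both libraries lowest on component 1, 13 lists passed, 3 upward and 10 downward, of which 1 was among the 5, growth-associated SAUR genes. The count was 13 without MIR394A_OE replicate 1, 8 without its replicate 2, 3 without Col-0 replicate 2, and 8, 9 and 8 without bin2-1 replicate 1, 2 and 3. With a pseudocount of 0.1 or 0.5 FPKM the Aux/IAA (0.0556 and 0.0566) and cell division calls (0.0542 and 0.0514) were lost, and with a minimum mean of 5 FPKM the cell division call (0.0736). Without 23 resistance and organelle genes taken in by symbol, the cytosolic ribosomal protein list passed upward (33 members, median 0.22, adjusted p = 0.00288; adjusted p = 0.812 with an estimated correlation), where the list as fixed did not (adjusted p = 0.0638). These 33 genes lost the call without Col-0 replicate 1 (0.141). They turned downward without MIR394A_OE replicate 1 (median -0.05) and without both libraries lowest on component 1 (median -0.11). Without MIR394A_OE replicate 2 their median was 0.53.

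The comparison of bin2-1 with Col-0 asks what differs in seedlings with a mutant form of the brassinosteroid signalling kinase BIN2. CYP85A2, which makes the most active brassinosteroid, rose from 2.44 ± 0.585 to 11.4 ± 1.51 FPKM (SD, n = 3 each), a log2 fold change of 1.85 (SE 0.19, limma, adjusted p = 0.0236). IAA29, an auxin-induced repressor, rose from 0.723 ± 0.352 to 6.20 ± 0.546 FPKM, a log2 fold change of 2.08 (SE 0.21, adjusted p = 0.0236). AGP1, an arabinogalactan protein of the cell surface, fell from 81.5 ± 36.7 to 11.9 ± 1.66 FPKM, a log2 fold change of -2.55 (SE 0.33, adjusted p = 0.0387). DREB26, an ethylene-response type transcription factor, fell from 130 ± 41.6 to 24.0 ± 11.6 FPKM, a log2 fold change of -2.43 (SE 0.34, adjusted p = 0.0446).

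Further genes that rose were PRN (2.48, SE 0.32), FUR1 (1.72, SE 0.20), AT1G47395 (1.57, SE 0.22), PP2-A8 (1.55, SE 0.21), AT1G65985 (1.28, SE 0.16) and AT3G50900 (1.2, SE 0.17), given as log2 fold changes. Further genes that fell were AT2G01180 (-2.12, SE 0.29), GeneID824912 (-1.79, SE 0.25), LGT8 (-1.60, SE 0.22), ABCG6 (-1.51, SE 0.20), AT1G28600 (-1.42, SE 0.18) and AT3G22620 (-1.37, SE 0.14). In all, 21 genes passed, 10 higher and 11 lower, and 3348 had an unadjusted p under 0.05, against 940 by chance. The median over all genes was 0.10 on the log2 scale. Rescaling by the median of ratios removed this shift and called 112 genes, 17 higher and 95 lower, and quantile scaling called 24, 7 higher and 17 lower. Without a filter 3 genes were called, CYP85A2, IAA29 and AT3G22620. Without trend and robust 9 were called, and AGP1, DREB26, PRN, AT1G47395, AT3G50900, AT2G01180, GeneID824912, LGT8 and AT1G28600 lost their calls, as did CYP706A1, CYP81D11 and ADT4. Quantile scaling ended those of AT1G47395, PP2-A8 and AT3G50900. Leaving out Col-0 replicate 3 or bin2-1 replicate 3 gave 180 and 171 calls, including all 21, and leaving out any other of the 8 libraries gave 0 in limma, with 1786 to 4227 genes at an unadjusted p under 0.05. A limma fit of the 2 groups alone gave 0 as well, with 4224 such genes. A fit without both libraries lowest on component 1 called 1 gene, which was not among the 21, so that CYP85A2 and IAA29 lost their calls there too, and estimated library weights called 10128.

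Genes of brassinosteroid biosynthesis passed upward as a list in bin2-1 (9 members, median 0.40, adjusted p = 0.0145; adjusted p = 0.496 with an estimated correlation; without Col-0 replicate 2, 0.0507; with a minimum mean of 5 FPKM, 0.0701). CYP85A2 was called over all genes, and 4 rose when adjusted over the list alone. Besides CYP85A2 these were DWF4, a rate-limiting hydroxylase (1.18, SE 0.18), CYP90D1 (1.04, SE 0.22) and ROT3 (0.64, SE 0.22). DWF4 was at 13.51 to 15.11 FPKM in bin2-1 and 5.65 to 6.02 in Col-0, higher in 3 of 3 libraries. Genes of brassinosteroid inactivation passed downward (5 members, median -0.27, adjusted p = 0.00588; adjusted p = 0.178 with an estimated correlation), and adjusted over the list alone 1 fell, UGT73C6 (-1.69, SE 0.42), a near copy of UGT73C5. Brassinosteroid signalling components did not pass (15 members, adjusted p = 0.793), with BES1 at -0.46 (SE 0.15) and BRL1 at 0.48 (SE 0.19).

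Auxin response genes passed upward in bin2-1 (17 members, 15 positive, median 0.62, adjusted p = 0.000780; adjusted p = 0.178 with an estimated correlation). IAA29 was called over all genes and 7 rose when adjusted over the list alone, among them IAA1 (1.2, SE 0.28), IAA5 (1.51, SE 0.41) and GH3.3 (1.55, SE 0.51). The Aux/IAA list with its 3 auxin response factors, which shares several of these genes, passed upward too (25 members, median 0.34, adjusted p = 0.0136; adjusted p = 0.407 with an estimated correlation), with 5 rising adjusted over the list alone, and passed without the 3 factors (adjusted p = 0.0185; adjusted p = 0.496 with an estimated correlation; without MIR394A_OE replicate 1 or 2, 0.0626 and 0.0603; without both libraries lowest on component 1, 0.0576). Growth-associated SAUR genes passed upward (15 members, 14 positive, median 0.77, adjusted p = 0.000780; adjusted p = 0.496 with an estimated correlation), and adjusted over the list alone 5 rose and 1 fell. SAUR62 (1.29, SE 0.32), SAUR15 (1.23, SE 0.35) and SAUR66 (1.11, SE 0.30) rose, and SAUR50 fell (-0.81, SE 0.20). The SAUR call was lost without both libraries lowest on component 1 (adjusted p = 0.0762), and with a minimum mean of 5 FPKM the SAUR (0.594) and Aux/IAA (0.2) calls were lost. PRE and BEE factors, bHLH proteins that promote growth downstream of brassinosteroids, passed upward (9 members, 9 positive, median 0.56, adjusted p = 0.0127; adjusted p = 0.178 with an estimated correlation). Adjusted over the list alone HBI1 (1.17, SE 0.28), IBH1 (0.56, SE 0.16) and PRE6 (0.67, SE 0.23) rose, and IBH1 is known as a growth inhibitor.

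**Figure D3:**
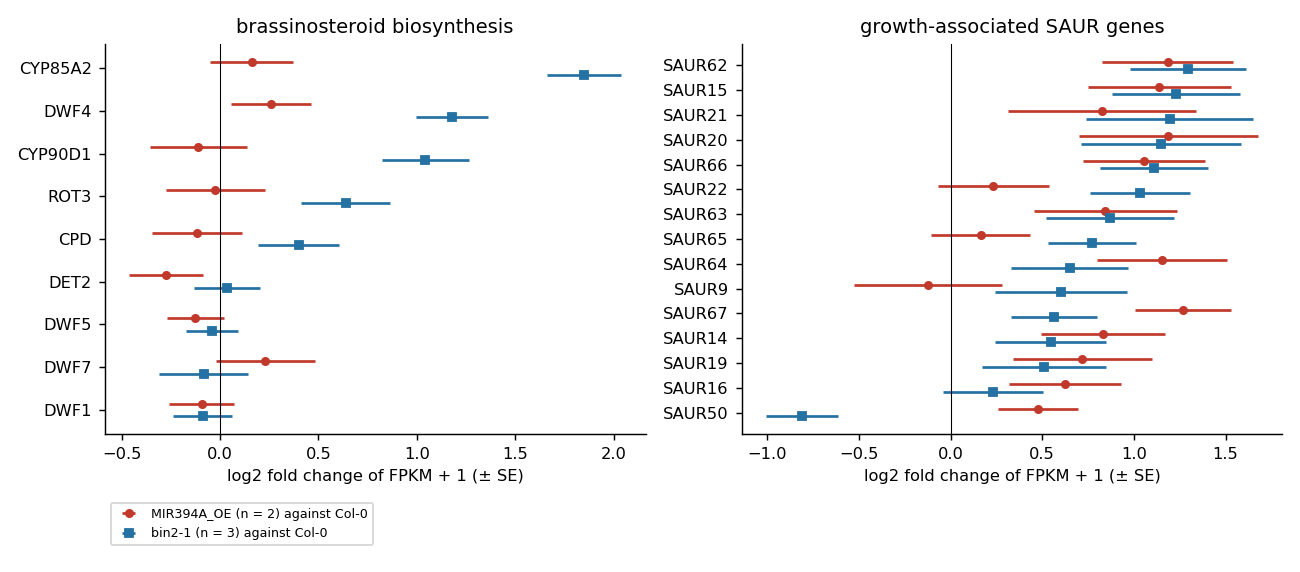
Log2 fold changes of FPKM + 1 against Col-0 with their SE (bars) for brassinosteroid biosynthesis genes (left) and growth-associated SAUR genes (right), in MIR394A_OE (circles, n = 2) and bin2-1 (squares, n = 3). CYP85A2 stands at 1.85 in bin2-1, and SAUR50 at -0.81 is the only SAUR below 0 there.

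The PIP and TIP list passed downward in bin2-1 (21 members, 1 positive, median -0.42, adjusted p = 4.86e-08; adjusted p = 0.255 with an estimated correlation). It holds aquaporins, water channels of the plasma membrane and vacuole, and also CAND1, a cullin regulator, and TIP1, an acyltransferase, which its symbols took in. Without these the 19 aquaporin genes passed downward, with 0 positive (median -0.44, adjusted p = 4.77e-09; adjusted p = 0.331 with an estimated correlation). None was called over all genes and 8 fell when adjusted over the list alone, among them PIP2A (-0.81, SE 0.22) and PIP1B (-0.69, SE 0.19). XTH genes, which remodel wall xyloglucan, passed downward (27 members, median -0.35, adjusted p = 0.000176; adjusted p = 0.319 with an estimated correlation). Adjusted over the list alone 4 fell, among them XTH22 (-3.15, SE 0.61) and EXGT-A3 (-0.84, SE 0.18). XTH22, also known as a touch-induced gene, ranged from 54.08 to 365.72 FPKM within bin2-1 and from 789.01 to 1617.64 in Col-0. The cell wall expansion list, which holds many of the XTH genes, passed downward (23 members, median -0.35, adjusted p = 0.0186; adjusted p = 0.178 with an estimated correlation; without Col-0 replicate 3, 0.177) with 1 lower adjusted over the list alone, XTH22. It missed the threshold under the median of ratios (0.0550) and quantile scaling (0.0513).

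Flavonoid and anthocyanin synthesis genes passed downward (10 members, 1 positive, median -0.61, adjusted p = 4.16e-07; adjusted p = 0.178 with an estimated correlation). None was called over all genes and 7 fell when adjusted over the list alone, with LDOX at -1.57 (SE 0.33), DFR at -1.32 (SE 0.32) and CHS at -0.59 (SE 0.15). Nuclear photosynthesis genes passed downward (24 members, 1 positive, median -0.32, adjusted p = 7.53e-07; adjusted p = 0.407 with an estimated correlation), with LHCB2.1 at -0.78 (SE 0.23) and LHCB2.2 at -0.66 (SE 0.22), which are near copies. None of these passed over all genes or adjusted over the list alone.

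The ERF list, ethylene-response factors with the translation release factors ERF1-1, ERF1-2 and ERF1-3 taken in by symbol, passed downward in bin2-1 (26 members, 10 positive, median -0.22, adjusted p = 0.00139; adjusted p = 0.178 with an estimated correlation). Without the release factors it passed with 23 members, 7 of them positive (median -0.23, adjusted p = 4.33e-05; adjusted p = 0.178 with an estimated correlation). When a library was left out this median ranged from -0.46, without bin2-1 replicate 3, to -0.21, without Col-0 replicate 2. Adjusted over the list alone 6 fell and 1 rose, with ERF4 at -1.40 (SE 0.31) and ERF11 at -2.44 (SE 0.59). Salicylic acid and defence genes passed downward (13 members, 1 positive, median -0.92, adjusted p = 0.00173; adjusted p = 0.448 with an estimated correlation). Adjusted over the list alone 2 fell, WRKY70 (-2.70, SE 0.59) and PAD4 (-1.12, SE 0.27), and 1 rose, FRK1 (1.18, SE 0.25). WRKY70 ranged from 19.1 to 44.65 FPKM in Col-0 and from 1.96 to 14.26 in bin2-1. Dark and sugar starvation genes passed downward (8 members, median -0.50, adjusted p = 0.0145; adjusted p = 0.523 with an estimated correlation), and adjusted over the list alone EXL2 (-0.96, SE 0.23), BT2 (-1.05, SE 0.25) and TPS8 (-1.07, SE 0.36) fell. This call was lost without Col-0 replicate 3 (0.0929) or bin2-1 replicate 1 (0.189) and under quantile scaling (0.0704). The MLP family passed downward (8 members, median -0.34, adjusted p = 0.0458; adjusted p = 0.673 with an estimated correlation), with MLP329 lower adjusted over the list alone (-0.66, SE 0.17). The MLP call was lost under the median of ratios (0.0629) and quantile scaling (0.120), with a pseudocount of 0.1 FPKM (0.0517), without a filter (0.0503), with a minimum mean of 5 FPKM and without both libraries lowest on component 1 (both 0.104), without Col-0 replicate 1 (0.229) or 3 (0.0560) and without bin2-1 replicate 2 (0.0540) or 3 (0.225). Of the 32 lists 15 passed, 5 upward and 10 downward, and the other 17 had adjusted p between 0.177, for all SAUR genes, and 0.996, for circadian clock genes. The clock list had 7 positive and 5 negative members, and opposite moves would not show in camera.

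**Figure D4:**
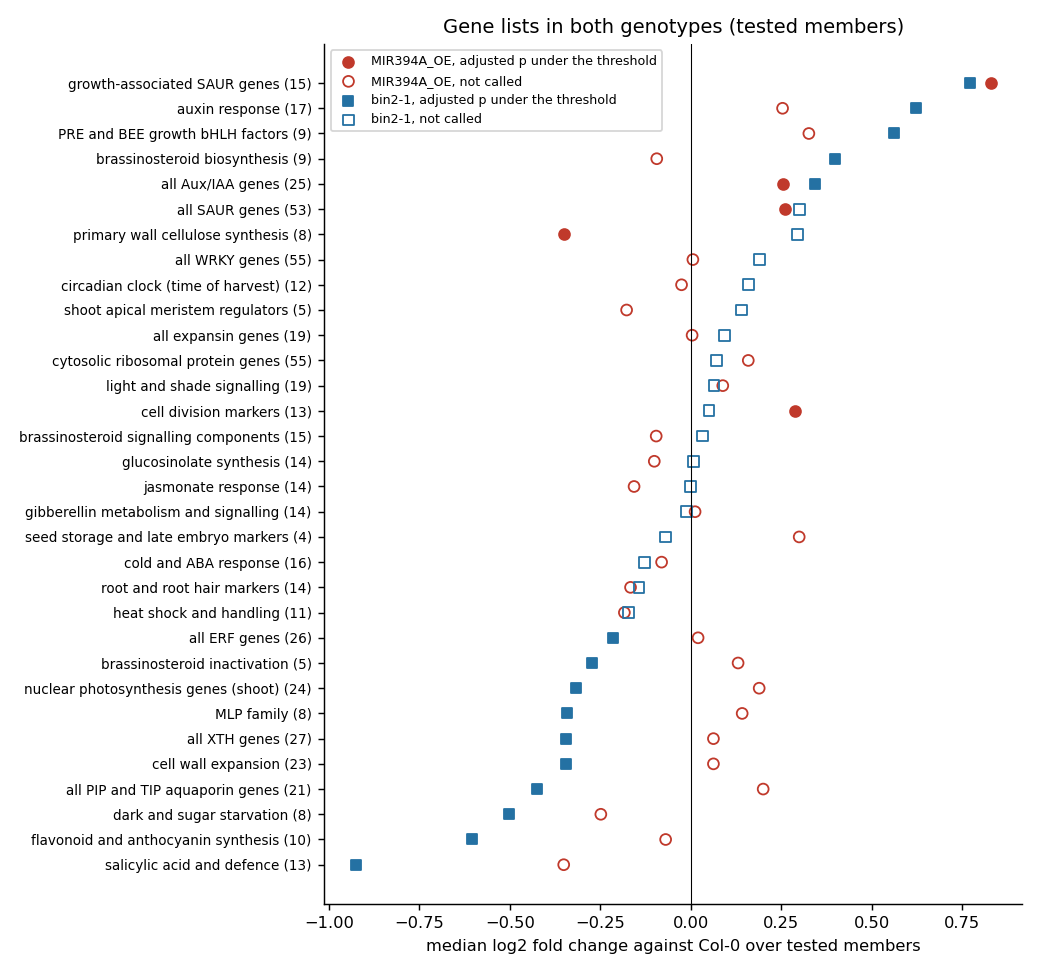
Median log2 fold change against Col-0 over the tested members of each list (number in brackets), for MIR394A_OE (circles) and bin2-1 (squares), filled where camera passed. Growth-associated SAUR genes stand at 0.83 and 0.77, and salicylic acid and defence genes at -0.35 and -0.92.

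The direct comparison of MIR394A_OE with bin2-1 tests where the lines differ from each other. MRD1 was lower in MIR394A_OE by a log2 fold change of -3.31 (SE 0.25, limma, adjusted p = 0.00334), HEI10 by -2.38 (SE 0.23, adjusted p = 0.0163) and ABCB19 by -2.14 (SE 0.22, adjusted p = 0.0201). CYP85A2 (-1.69, SE 0.21) and IAA29 (-1.83, SE 0.24) were lower as well, at 2.82 ± 0.262 and 1.05 ± 0.474 FPKM in MIR394A_OE (SD, n = 2) against 11.4 ± 1.51 and 6.20 ± 0.546 in bin2-1 (SD, n = 3). Higher in MIR394A_OE were AT5G50915 (1.82, SE 0.24), BETA-OHASE 2 of carotenoid synthesis (1.72, SE 0.20), CYP81D11 (1.66, SE 0.20) and AT3G06770 (1.38, SE 0.18). IAA29 kept its call in 2 of 10 other settings and CYP85A2 in 5 of 11. Both lost it with a pseudocount of 0.1 FPKM (adjusted p = 0.0786 and 0.0501) or 0.5 FPKM, without a filter (0.0721 and 0.0652), with library weights and without both libraries lowest on component 1 (0.405 and 0.269). AT5G50915 kept its call in 3 of 11 settings and AT3G06770 in 4, BETA-OHASE 2 and CYP81D11 in 7 each, lost without a filter (both 0.0589) and without both libraries lowest on component 1 (both 0.322), and HEI10 in 9, lost in the latter (0.196). MRD1 kept its call in 8 of 8 fits that left out a library. ABCB19 lost it without Col-0 replicate 2 or bin2-1 replicate 1 or 2 (0.0631, 0.139 and 0.172). HEI10 lost it there (0.0602, 0.074 and 0.146) and without MIR394A_OE replicate 1 (0.196), as did BETA-OHASE 2, CYP81D11, CYP85A2, IAA29, AT5G50915 and AT3G06770 in these same 4 fits. In all 10 genes passed, 4 higher and 6 lower, with 3571 at an unadjusted p under 0.05, against 940 by chance. The median of ratios gave 8 higher and 6 lower and quantile scaling 10 and 5. The count was 2307 without MIR394A_OE replicate 2, 79 without bin2-1 replicate 3, 39 without Col-0 replicate 3 and 21 without Col-0 replicate 1. It was 2 without MIR394A_OE replicate 1 and 1 without Col-0 replicate 2 or bin2-1 replicate 1 or 2, and 0 in a limma fit of the 2 groups alone, with 3133 genes at an unadjusted p under 0.05. Without both libraries lowest on component 1, 2 genes were called.

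The PIP and TIP list with CAND1 and TIP1 passed higher in MIR394A_OE than in bin2-1 (21 members, median 0.62, adjusted p = 3.14e-07; adjusted p = 0.454 with an estimated correlation), as did its 19 aquaporin genes (median 0.65, adjusted p = 6.15e-09; adjusted p = 0.503 with an estimated correlation), 10 of them adjusted over the list alone, with PIP3 at 0.92 (SE 0.20) and PIP1;4 at 0.87 (SE 0.19). The median of the 19 was 0.38 without MIR394A_OE replicate 1 and 0.91 without its replicate 2. Nuclear photosynthesis genes passed higher (24 members, median 0.45, adjusted p = 1.62e-06; adjusted p = 0.520 with an estimated correlation), 9 of them adjusted over the list alone, with LHCB2.1 at 1.28 (SE 0.26). LHCB1.1 was at 5254.98 FPKM in MIR394A_OE replicate 1 and 2508.8 in replicate 2, against 1359.54 to 2055.39 in bin2-1. Flavonoid synthesis genes passed higher (10 members, median 0.53, adjusted p = 0.000346; adjusted p = 0.403 with an estimated correlation), 5 of them adjusted over the list alone, with LDOX at 2.27 (SE 0.36). XTH genes passed higher (27 members, median 0.50, adjusted p = 0.000537; adjusted p = 0.503 with an estimated correlation), 5 of them adjusted over the list alone, with XTH22 at 3.27 (SE 0.68).

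Brassinosteroid biosynthesis genes passed lower in MIR394A_OE than in bin2-1 (9 members, median -0.52, adjusted p = 0.00814; adjusted p = 0.520 with an estimated correlation; without MIR394A_OE replicate 2, 0.137). CYP85A2 was called over all genes, and 3 were lower adjusted over the list alone, the other two being DWF4 (-0.92, SE 0.20) and CYP90D1 (-1.15, SE 0.25). Brassinosteroid inactivation genes passed higher (5 members, median 0.46, adjusted p = 0.0112; adjusted p = 0.403 with an estimated correlation; without MIR394A_OE replicate 2, 0.0533), 1 of them adjusted over the list alone, UGT73C6. The MLP family (median 0.41, adjusted p = 0.0112; adjusted p = 0.713 with an estimated correlation), the ERF list (0.15, adjusted p = 0.0194; adjusted p = 0.454 with an estimated correlation) and the cell wall expansion list (0.42, adjusted p = 0.0348; adjusted p = 0.403 with an estimated correlation) passed higher, with 1, 0 and 3 members adjusted over the list alone. Without the release factors the ERF list passed at a median of 0.57 (adjusted p = 0.00598; adjusted p = 0.503 with an estimated correlation). This median fell to 0.15 without MIR394A_OE replicate 1, and likewise without both libraries lowest on component 1. The 33 cytosolic ribosomal protein genes also passed higher (median 0.13, adjusted p = 0.0271; adjusted p = 0.886 with an estimated correlation), but not under quantile scaling (0.484) or without bin2-1 replicate 3 (0.376). Their median was -0.13 without MIR394A_OE replicate 1 or both libraries lowest on component 1, and 0.47 without MIR394A_OE replicate 2. Primary wall cellulose genes passed lower (median -0.61, adjusted p = 0.0198; adjusted p = 0.780 with an estimated correlation), with 0 members adjusted over the list alone. Without MIR394A_OE replicate 1 the MLP, ERF, cell wall expansion and cellulose lists as fixed lost their calls (0.441, 0.136, 0.1 and 0.841), as they did without both libraries lowest on component 1 (0.595, 0.154, 0.0604 and 0.758), and cell wall expansion missed the threshold under both rescalings (0.0593 and 0.0624) and without MIR394A_OE replicate 2 (0.102). The MLP and cellulose calls were also lost without bin2-1 replicate 3 (0.0572 and 0.1), and the ERF and cell wall expansion calls without a filter (both 0.0538). Of the 32 lists 10 passed, 8 higher and 2 lower, and growth-associated SAUR genes did not differ by this test (adjusted p = 0.541). The circadian clock list did not pass (12 members, adjusted p = 0.949), though adjusted over the list alone LHY (0.84, SE 0.20), CCA1 (1.06, SE 0.27) and RVE8 were higher and PRR5 and ELF3 lower in MIR394A_OE. Such opposite moves within a list cannot show in camera.

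The last comparison asks whether the lines share a response. No gene was called in both comparisons with Col-0. With so few calls the overlap expected for independent lists was 0 genes higher and 0.00117 lower, so its absence says little. Across genes the fold changes correlated at r = 0.15 (Spearman 0.12). Simulated libraries without group differences, with both lines set against the same simulated Col-0 libraries, gave r = 0.45. The covariance was 0.0185 against 0.0290 simulated, a difference of -0.0106. The simulation used the spread pooled over the 3 groups and noise independent between genes. It held no shift of the median over all genes, which was 0.04 in MIR394A_OE and 0.10 in bin2-1. At an unadjusted p under 0.05, 200 genes were higher in both and 46 lower in both, against 91.1 and 89.9 simulated and 65.9 and 20.4 for independent lists. For the reasons given, the simulated counts are no close reference for the 200 and 46. With 3 Col-0 libraries no division leaves at least 2 on each side, so part of any excess over the counts for independent lists may come from the shared controls. Dividing them into 1 library for one line and 2 for the other, in each of the 6 ways, gave a covariance of -0.0669 to 0.0188 with a mean of -0.0174, above 0 in 3 of the 6. Without MIR394A_OE replicate 2 r was -0.11, and without replicate 1 it was 0.43.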

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

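The threshold of 0.10, the library weights, the families without members of other families and the fit without both libraries lowest on component 1 were chosen after seeing the data. MIR394A_OE against Col-0 called 2 genes in most settings, 0 with only these 2 groups in the fit and 0 to 2 when a library was left out. For bin2-1 against Col-0, 21 genes became 3 without a filter, 112 after rescaling by the median of ratios, 9 without trend and robust, 0 with only the 2 groups and 0 to 180 when a library was left out. For MIR394A_OE against bin2-1, 10 genes became 6 with a pseudocount of 0.1 or 0.5, 3 without a filter, 0 with only the 2 groups and 1 to 2307 when a library was left out. Fewer residual degrees of freedom go with the 2-group fits. The cause of the other changes was not tested. A threshold of 0.10 called 3, 293 and 75 genes. Leaving out both libraries lowest on component 1 called 2, 1 and 2. Estimated library weights called 2, 10128 and 4, but their estimation stopped before convergence and put weights of 8.56 and 8.09 on Col-0 replicate 2 and bin2-1 replicate 2, against at most 0.713 on the others, so the Col-0 and bin2-1 means rest largely on 1 library each.

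In MIR394A_OE against Col-0, 5 lists became 3 with a pseudocount of 0.1 or 0.5, 8 without a filter, 13 without both libraries lowest on component 1, and 3 to 13 when a library was left out. The ranges when a library was left out were 14 to 15 lists for bin2-1 and 8 to 13 between the lines. The lists behind the bin2-1 count were not the same in each fit. The cell wall expansion, dark and sugar starvation and MLP lists each lost their call in some of them. With an estimated correlation 0 lists passed in each comparison, and 0, 6 and 3 had an unadjusted p under 0.05. Primary wall cellulose genes turned upward in MIR394A_OE without its replicate 1 (adjusted p = 0.405), the range over the libraries left out being 0.000123 to 0.405. The correlation of the 2 responses ranged from -0.11, without MIR394A_OE replicate 2, to 0.43. LCR stayed negative and uncalled in all settings, at -0.32 to -0.17. Where a library was left out of MIR394A_OE, the lone library is assumed to vary like the other groups.

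Whether libraries of the same replicate number belong together is not settled by these values. Deviations from the group mean correlated at 0.36, 0.08 and 0.32 between the libraries of replicate 1. The correlations were 0.27, -0.20 and 0.03 between those of replicate 2, and -0.11 between the Col-0 and bin2-1 libraries of replicate 3. The 2 MIR394A_OE libraries deviate from their mean as mirror images. The values of 0.36, 0.32, 0.27 and 0.03 therefore all rest on 1 difference between these 2 libraries. Libraries of unlike replicate number were not compared in this way. Replicate 1 also lay highest of its group on component 2 in Col-0, MIR394A_OE and bin2-1. A difference shared by the libraries of replicate 1 therefore stays open. With the replicate block 2, 32 and 9 genes were called in the 3 comparisons, 2, 12 and 5 of them shared with the calls without it, and 6, 16 and 10 lists. The calls absent under the block were CYP706A1, AT1G47395, AT2G01180, GeneID824912, PRN, CYP81D11, LGT8, DREB26 and ADT4 in bin2-1, and IAA29, AT5G50915, CYP81D11, AT3G06770 and CYP71B7 between the lines. The cell division list in MIR394A_OE was also absent (adjusted p = 0.105). Families without members of other families gave 6, 15 and 11 lists, including the 5, 15 and 10. At the estimated depth 3 reads on 1 kb are worth 0.268 to 0.310 FPKM, which limits what can be said of genes near that level.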

Other observations

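The tests of rescaling and of neighbouring genes, both tests of the iron genes and the test of correlated SAUR members were chosen after the result was seen.

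Several lists that did not pass as a whole held single members that passed when adjusted over the list alone in bin2-1 against Col-0. Among cold and ABA response genes RD29A (1.80, SE 0.38) and ERD10 (0.66, SE 0.19) were higher, and RAB18 (-0.87, SE 0.27) and HAI1 (-0.62, SE 0.19) were lower. Among heat shock and handling genes HSP101 (0.65, SE 0.18) and HSP90.1 (0.55, SE 0.15) were higher and the touch-induced TCH2 (-1.59, SE 0.40) was lower. GASA6, a gibberellin-induced gene, was lower (-1.18, SE 0.29), and WRKY29 was higher (1.81, SE 0.27) while WRKY15 was lower (-0.89, SE 0.16). None of these passed over all genes.

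MRD1, HEI10 and ABCB19 stood out in MIR394A_OE. A direct action of miR394 needs a complementary site, and the lowest mismatch score over the 3 genes was 6.0, where LCR has 1.0 and a limit of 4 was set in advance. Over 63 tested genes with a site scoring 4 or less, the median log2 fold change was 0.01. Rescaling left all 3 genes low, with the value nearest to 0 at -1.94. The median log2 fold change over all genes was only 0.04, so this outcome was settled beforehand. Library scaling of that size could hardly account for falls as large as these. A sequence difference local to the 2 sites, in the line itself, may still be a candidate explanation: 0 of 6 flanking genes of MRD1 and HEI10 were below -1, but ABCB19 had no tested gene within 3 loci and regulation of the genes themselves would look alike, so the 2 cannot be told apart.

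The iron-response genes AT1G13609 (2.03 in each line, SE 0.29 and 0.26), AT1G47395, BHLH100 and AT2G14247 had positive fold changes in both lines, but in MIR394A_OE none passed (limma, adjusted p = 0.233, 0.719, 0.873 and 0.873) and in bin2-1 the last 2 did not (0.174 and 0.137). Over 16 other tested iron-deficiency genes the median was 0.36 in MIR394A_OE and 0.26 in bin2-1, where the unadjusted p of camera was 0.000793 and 0.291 at the preset correlation and 0.0523 and 0.462 with an estimated correlation, so a response across these genes may be present in the first line and was not detected in the second. The 4 genes did not differ between the lines by the test (smallest adjusted p = 0.224), which would also follow from a feature of the Col-0 libraries shared by both comparisons. With 3 Col-0 libraries these explanations cannot be told apart. The Col-0 levels that both comparisons share were also low. AT1G13609 lay at 0.26 to 0.51 FPKM in Col-0, near the floor given by the estimated depth, so this baseline rests on very few reads. BHLH100 lay at 0.75 to 1.4 FPKM in Col-0, AT2G14247 at 0.77 to 1.1 and AT1G47395 at 2.24 to 3.38.

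Growth-associated SAUR genes passed upward as a list in both lines at the preset correlation only. Low values in Col-0 replicate 1 alone do not account for this, since without it the list median kept a ratio of 0.694 in MIR394A_OE and 0.863 in bin2-1. Members that move together between replicates may account for the strength of the call, as the smaller p with an estimated correlation was 0.061 and the correlation was estimated at 0.450. The list did not differ between the lines (camera, adjusted p = 0.541). This would also follow from low SAUR values in the Col-0 libraries that both comparisons share. A shared effect of the 2 genotypes on SAUR genes stays open as a hypothesis, and 3 Col-0 libraries cannot tell the 2 apart.

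Other splits of the 3 Col-0 and 3 bin2-1 libraries were compared with the real one. The real split called 21 genes and the highest of the others 31, and 2 of the 10 splits, counting the real one, called at least 21. At an unadjusted p under 0.05 the real split gave 3348 genes and the others 85 to 1271. The split with 31 set Col-0 replicate 1, bin2-1 replicate 1 and bin2-1 replicate 2 against the rest. For lists, at the preset correlation, the real split called 15 and the others 4 to 15. A count of 15 was reached by 3 of the 10 splits, counting the real one. Splits that mixed the genotypes thus also called lists. With 10 splits the share cannot fall below 0.05.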
